A study of Mus musculus with 24 samples.

How the data were processed

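RNA of the plantaris muscle was measured on 24 Affymetrix whole-transcript arrays, 1 array per replicate, in 4 groups of 6 biological replicates: untreated and overloaded wildtype mice, and untreated and overloaded Mstn-/- mice, all aged 3 months. Overload was produced, per the labels' protocols, by surgical removal of the soleus and a major part of the gastrocnemius on both sides under pentobarbitone (50 mg/kg), and control mice had no operation. The muscle of 1 side was used, 1000 ng of total RNA went into each labelling, ribosomal RNA was removed and biotin-labelled sense-strand targets were made. How long the overload lasted, the time of day of sampling and the dates of surgery, labelling or scanning are not given in the sources used here.

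The authors' values are intensities per probe set after RMA (background correction, normalization across arrays and summary per probe set), per the submitters' processing notes, which give no version. The deposited intensities run from 4.72 to 25588.9 with array medians between 139 and 147 and so are on a linear scale. The analysis plan had assumed log2 values, and log2 of the deposited intensities was taken without a pseudocount.

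The table holds 34760 probe sets. Those with exactly 1 gene symbol (21640) were used. The 1321 with several symbols and the 11799 without a symbol were left out of the comparisons, and the latter are summarised in the closing section. Of the symbols' probe sets 21553 matched a RefSeq table of mouse assembly GRCm38.p6, used for names only, and 87 did not. The build behind the array annotation is not named, so no coordinates are given. Of several probe sets of a gene the one with the highest mean over all arrays was taken, giving 19937 genes. A gene was tested if the mean of at least 1 group was above the 30th percentile of all annotated probe sets (intensity 98.9), which left 14499 genes. For Ccl8, Ms4a7, Ccna2, Gdap1, Inmt, Lgi1 and Mettl21e a fold in the text has a group mean below this level on 1 side, so its size is uncertain. So is the size of the difference in response of Cxcl13, Ostn, Acan, Gdap1, P4ha3, Lgi1 and Kcnf1, each of which has at least 1 group mean below it.

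Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 24 arrays, which pools the spread (20 residual degrees of freedom), followed by eBayes and Benjamini-Hochberg adjustment over the genes of each comparison, with a threshold of 0.05 on the adjusted p. The 5 comparisons were overload against no overload in wildtype and in Mstn-/-, Mstn-/- against wildtype without and under overload, and the difference between the genotypes in the overload response. Fold changes are ratios of group geometric means. Of 36 gene lists written before the data were examined, 35 had at least 3 genes tested. They were tested with camera at the preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 35 lists. A list is called when camera at the preset correlation passes, and counts of its genes use the adjusted p over all 14499 genes unless adjusted over the list alone.

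Genes are named by a rule written before the data were examined: Mstn in every comparison, then, among genes past the threshold whose groups do not overlap and whose symbol is not that of a predicted model, the 10 largest rises and 10 largest falls of each comparison (5 and 5, without the overlap condition, for the difference between responses), and for each list described up to 4 members with the smallest adjusted p, 2 that rose and 2 that fell. Post hoc lists of clock, glucocorticoid-responsive and imprinted genes, written after the values were seen, appear only in the closing section. Relations between comparisons use Pearson and Spearman correlations across genes and a total least squares slope. For comparisons that share the untreated wildtype arrays, the covariance due to shared controls came from 100 simulations of unchanged groups. The correlation without a shared control came from 20 splits of those arrays.

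The fit was tested on simulated data before use, with 200 of 14499 genes changed in each of 5 runs for overload in wildtype. It recovered 28.4% of genes changed by 0.2 on the log2 scale, 62.4% at 0.3, 94.8% at 0.5 and 100% at 1, with 4.42% of calls false. The simulated noise was independent between genes. Genes on the real arrays vary together (estimated correlation 0.69 in the oxidative phosphorylation list) and far more of them were called, so these shares need not carry over. Array medians, principal components and pairwise differences between arrays were checked, and at most 0.0201% of values were identical between 2 arrays. Alternatives were another quantile normalization, a shift of the arrays to the same median, no filter and a stricter filter, the mean of all probe sets of a gene, every probe set, a trended and robust variance model, array weights, the replicate number as a block, a minimum fold of 1.5, fits with the compared groups alone, and each array left out in turn. Plots were made with Python 3.11.15 and matplotlib 3.10.9.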

Results

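Transcript levels were measured in the plantaris, an ankle extensor and toe flexor muscle of the hindlimb, of wildtype mice and of Mstn-/- mice, which lack functional myostatin, a secreted TGF-beta family protein that restrains muscle growth. In each genotype 1 group was left untreated and in 1 group the plantaris was overloaded by surgery that took away its synergists, the soleus and most of the gastrocnemius. Each of the 4 groups had 6 biological replicates, giving 24 whole-transcript arrays from mice aged 3 months. The series title names remodelling of the extracellular matrix and muscle force under overload as its subject. The median intensity per array lay between 139 and 147, and 14499 genes were tested. The number of arrays limits the precision, and the median standard error of a difference between 2 groups was 0.067 on the log2 scale. The first principal component of the tested genes held 72.7% of the variance and set overloaded apart from untreated arrays, and the second held 8.42% and set the genotypes apart.

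Mstn itself was lower on the Mstn-/- arrays without overload. Its mean log2 intensity was 10.25 ± 0.11 (SD, n = 6) in untreated wildtype and 8.93 ± 0.31 in untreated Mstn-/- muscle, a 2.51-fold difference (limma adjusted p = 2.7e-08), with no overlap between the arrays of the 2 groups. Under overload it fell 3.62-fold in wildtype (adjusted p = 1.8e-12) and 1.60-fold in Mstn-/- muscle (adjusted p = 5.6e-05), and the overloaded groups, at 8.40 ± 0.19 and 8.25 ± 0.30, did not differ by the test (log2 difference -0.15 ± 0.13, SE, adjusted p = 0.39). Signal remained on the Mstn-/- arrays, and whether the probe set lies in the deleted part of the gene is not given in the sources used here, so the level checks the genotype labels of the untreated groups but not those of the overloaded groups.

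**Figure D1:**
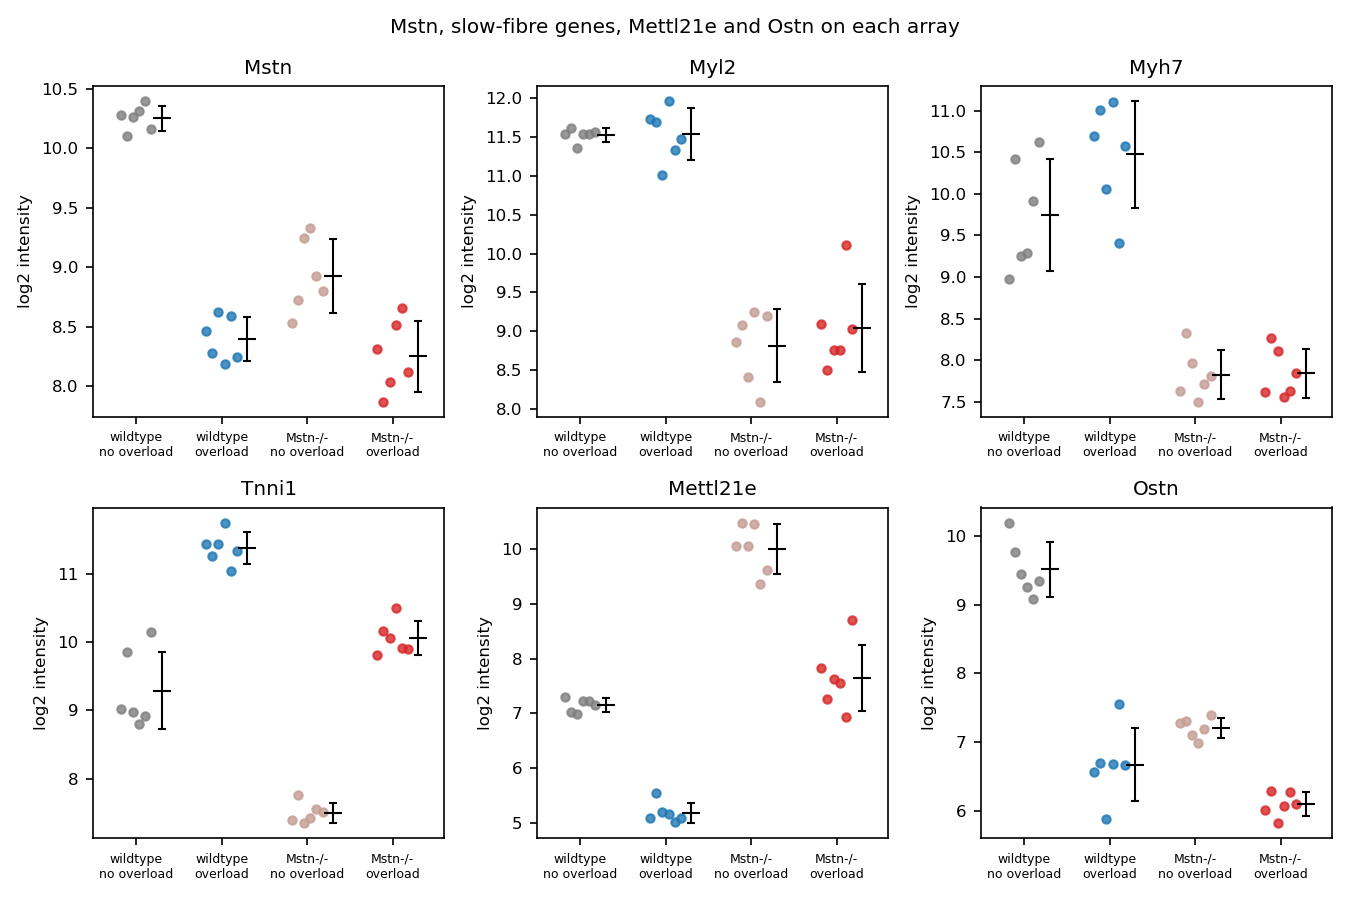
Log2 intensity (vertical axis) of Mstn, of the slow-fibre genes Myl2, Myh7 and Tnni1, and of Mettl21e and Ostn on each of the 24 arrays, by group (horizontal axis), 1 point per array with the group mean and SD in black. Mean Myl2 is 11.53 and 11.54 in the wildtype groups and 8.81 and 9.04 in the Mstn-/- groups.

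The first comparison asks what overload changes in wildtype muscle. Overloaded plantaris had far higher transcript levels of extracellular matrix, macrophage and embryonic contractile genes, and lower levels of most tested genes of the energy metabolism lists. C1qtnf3, which encodes a secreted C1q/TNF-related protein, rose 25.6-fold (log2 4.68 ± 0.19, SE, n = 6 per group), and the imprinted gene Mest rose 21.4-fold (log2 4.42 ± 0.13). Ostn, which encodes the secreted peptide osteocrin or musclin, fell 7.16-fold (log2 -2.84 ± 0.18). Of the 14499 genes, 9560 passed the limma test at an adjusted p of 0.05, 4396 higher and 5164 lower under overload, and 1194 of them changed at least 2-fold, 863 upward and 331 downward.

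Matrix genes led the rises. All 16 of 16 interstitial collagen genes rose, with a median rise of 4.41-fold, Col3a1 by 7.49-fold and Col6a3 by 6.14-fold. 18 of 19 matrix glycoprotein genes rose, among them fibronectin (Fn1, 6.13-fold) and Thbs3 (4.65-fold), while vitronectin (Vtn) fell 1.15-fold. Of the matrix proteases and their inhibitors, 19 of 22 rose, with the collagenolytic membrane protease Mmp14 at 8.60-fold and the gelatinase Mmp2 at 5.53-fold, and the metalloprotease inhibitor Timp4 fell 5.87-fold. Of 18 collagen processing and cross-linking genes 14 rose, with the prolyl hydroxylase subunit P4ha3 up by 3.47 on the log2 scale and the lysyl oxidase relative Loxl1 up 4.40-fold, and the procollagen proteinase enhancer Pcolce2 fell 1.66-fold. The proteoglycans Vcan and Aspn rose 9.35-fold and 8.61-fold, 13 of 15 proteoglycan genes rising, and 10 of 13 basement membrane genes rose, including the laminin chain Lamb1 (3.83-fold). 9 of 10 tendon marker genes rose, tenomodulin (Tnmd) by 4.56-fold and Thbs4 by 2.60-fold. In the order named, the camera adjusted p of these 7 lists was 6.1e-12, 1.3e-10, 2.7e-08, 3.0e-07, 2.1e-05, 3.1e-06 and 8.4e-04, and adjusted p = 0.13, 0.13, 0.13, 0.14, 0.14, 0.13 and 0.25 with an estimated correlation. Their counts of higher genes adjusted over the list alone were the same.

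Secreted regulators of matrix and Wnt signalling were among the largest single rises, with Sfrp2 up 15.3-fold, Cthrc1 up 14.2-fold and periostin (Postn) up 10.5-fold. The chemokine Ccl8 rose 10.5-fold and Wfdc17, a secreted protein of myeloid cells, 9.63-fold. The imprinted non-coding RNA Meg3 rose 9.72-fold. Markers of some other cell types rose with the matrix. 17 of 18 macrophage markers rose, with a median of 4.02-fold (Lyz2 6.02-fold, Laptm5 5.07-fold), as did 9 of 11 markers of fibro-adipogenic progenitors, the resident fibroblast-like cells (Mfap5 5.60-fold, Pi16 2.78-fold), while gelsolin (Gsn) fell 1.35-fold. 9 of 12 endothelial markers rose by less, with a median of 1.27-fold (Pecam1 1.67-fold), and the receptor Flt1 fell 1.65-fold. 14 of 16 proliferation genes rose, the cyclin Ccna2 by 5.10-fold and Mki67 by 3.83-fold. The camera adjusted p of the macrophage, progenitor, endothelial and proliferation lists was 8.0e-10, 3.5e-05, 0.033 and 1.8e-05, and adjusted p = 0.14, 0.14, 0.40 and 0.14 with an estimated correlation. Adjusted over the list alone, 17, 9, 9 and 14 of their genes were higher.

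Contractile genes moved both ways. The embryonic myosin heavy chain Myh3 rose 11.3-fold and cardiac troponin T (Tnnt2) 4.36-fold, 9 of 11 developmental contractile genes rising and Nrap falling 1.21-fold. Of 14 slow-fibre genes 9 rose and 3 fell, with slow troponin I (Tnni1) up 4.25-fold and Tpm3 up 2.47-fold, and phospholamban (Pln) and the slow myosin light chain Myl3 down 1.58-fold and 1.94-fold; as a list they missed the threshold (camera adjusted p = 0.057, 9 higher and 4 lower adjusted over the list alone). 11 of 15 fast-fibre genes fell, including parvalbumin (Pvalb, 1.75-fold) and Actn3 (1.72-fold). Among satellite cell and myogenic genes the fusion factor Mymk rose 3.82-fold, and 8 of 17 rose. Growth factor genes did not move as 1 block: Igf2 rose 7.02-fold and Igfbp4 5.79-fold while Irs2 fell 1.80-fold and Akt2 1.52-fold, so that 9 genes of that list rose and 8 fell (camera adjusted p = 0.28); the median was -0.05 and the mean 0.38 on the log2 scale. Of 30 TGF-beta and activin signalling genes 16 rose and 6 fell. Follistatin-like Fstl1 rose 6.89-fold and the receptor Tgfbr2 2.92-fold, and Acvr2b, a receptor of myostatin, fell 1.60-fold with Mstn. The camera adjusted p of the developmental, fast-fibre, myogenic and TGF-beta lists was 6.8e-04, 0.0027, 0.0063 and 0.014, and adjusted p = 0.13, 0.40, 0.14 and 0.14 with an estimated correlation. Their counts adjusted over the list alone were the same, and in the growth signalling list 9 rose and 9 fell adjusted over the list alone.

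Genes of energy metabolism fell. All 26 of 26 genes of oxidative phosphorylation and the citric acid cycle fell, with a median of 1.55-fold (Idh3a 2.06-fold, Cox5a 1.67-fold), all 18 of 18 fatty acid oxidation genes fell (lipoprotein lipase Lpl 2.19-fold, Eci1 1.98-fold), and 15 of 16 glycolysis and glycogen genes fell (the phosphorylase kinase subunit Phka1 3.13-fold, Pgm1 2.58-fold), the exception being Pgm2, which rose 2.37-fold. The transcriptional regulators Ppara and Ppargc1a fell 3.20-fold and 2.47-fold, 10 of 12 genes of their list falling. Several of the largest single falls encode metabolic enzymes or mitochondrial proteins: the glycolytic regulator Pfkfb3 fell 4.92-fold, the mitochondrial alanine aminotransferase Gpt2 4.98-fold, Adhfe1 5.32-fold, Gdap1 4.94-fold and Mss51 5.83-fold. The kinase Mylk4, the phospholipase Plcd4 and the methyltransferase Inmt fell 5.31-fold, 5.01-fold and 5.66-fold. By camera, adjusted p of the 4 metabolic lists in this order was 1.1e-07, 3.5e-07, 3.1e-05 and 7.8e-04, and adjusted p = 0.26, 0.22, 0.25 and 0.14 with an estimated correlation. Counts adjusted over the list alone were the same for these 4 lists.

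The complement and interferon, chemokine and cytokine, immediate early and heat shock, integrin and sarcolemmal linkage, and smooth muscle and pericyte lists were also called higher, with 10 of 11, 13 of 15, 11 of 15, 13 of 23 and 6 of 11 genes higher (camera adjusted p = 1.7e-04, 1.8e-04, 0.0085, 0.042 and 0.047, and adjusted p = 0.22, 0.14, 0.23, 0.40 and 0.40 with an estimated correlation). The atrophy and proteolysis list was called lower, with 10 of 19 genes lower and 12 adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.23 with an estimated correlation). The ribosome biogenesis, adipocyte, mast cell, cartilage and bone, lymphocyte, denervation, neutrophil, and Schwann cell and nerve lists were not called, at camera adjusted p from 0.11 to 0.71. Of the 35 lists 25 were called by camera, 0 of them with an estimated correlation (10 at an unadjusted p of 0.05), and fry, which asks whether a list's genes move one way on balance, called 34. Control mice were untreated, so overload and surgery differ together between these groups. With the arrays shifted to the same median, 3633 genes were higher and 7004 lower, against 4396 and 5164 as deposited.

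**Figure D2:**
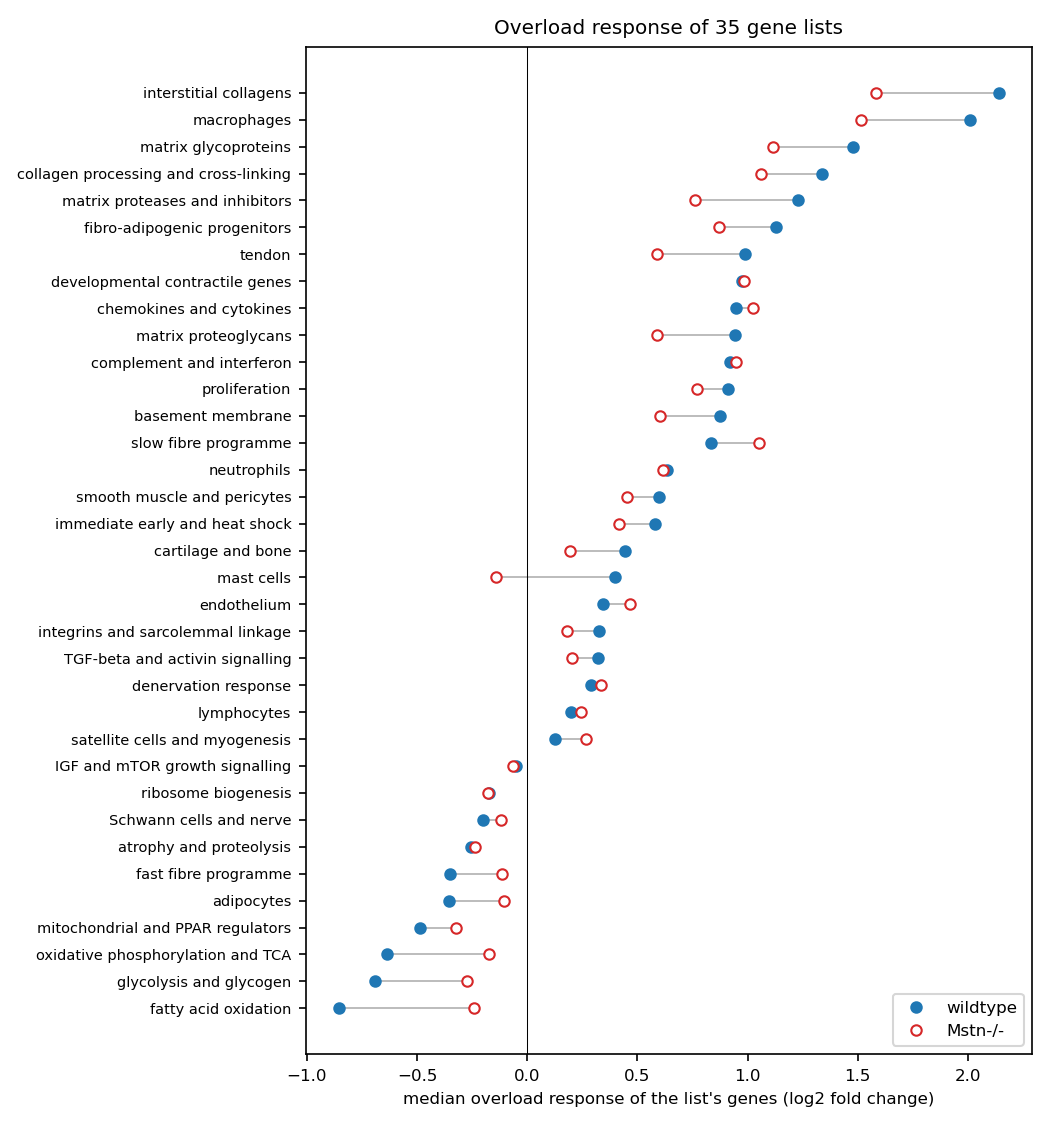
Median log2 fold change under overload (horizontal axis) of each of the 35 gene lists (vertical axis) in wildtype, filled circles, and in Mstn-/- muscle, open circles, with a line joining the 2 medians of a list. The medians of fatty acid oxidation are -0.85 in wildtype and -0.24 in Mstn-/- muscle.

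The second comparison asks what overload changes in muscle without myostatin. The largest rises were largely the wildtype ones, in matrix, inflammatory and embryonic contractile genes, and the falls in metabolic genes were fewer. Mest rose 22.4-fold (log2 4.48 ± 0.13, SE, n = 6 per group), C1qtnf3 17.8-fold (log2 4.16 ± 0.19) and Postn 15.8-fold (log2 3.98 ± 0.21). The largest fall was that of Odf3l2, 8.40-fold, and the ubiquitin ligase Fbxo32 (atrogin), a marker of muscle atrophy, fell 3.80-fold. In all 8789 of 14499 genes passed the test, 3932 higher and 4857 lower, and 667 changed at least 2-fold, 561 upward and 106 downward.

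All 16 of 16 interstitial collagens rose, with a median of 2.99-fold (Col3a1 4.96-fold, Col6a3 4.27-fold), and so did all 19 of 19 matrix glycoproteins (Mfap4 5.67-fold, Fn1 4.49-fold). Tenascin C (Tnc), another matrix glycoprotein, rose 7.28-fold, and the secreted Wnt modulators Sfrp2 and Sfrp1 rose 10.3-fold and 7.44-fold, with Cthrc1 at 7.71-fold. 17 of 22 protease and inhibitor genes rose (Mmp14 4.50-fold, Mmp2 2.78-fold) and Timp4 fell 2.30-fold. 8 of 10 tendon markers rose, Tnmd by 5.04-fold. 16 of 18 macrophage markers rose (Ms4a7 6.98-fold, Laptm5 3.82-fold), while the scavenger receptor Cd163, a marker of resident macrophages, fell 1.36-fold. Ccl8 and Wfdc17 rose 8.18-fold and 7.84-fold, and the interferon-inducible chemokine Cxcl9 5.30-fold. 10 of 12 endothelial markers rose (Esam 1.60-fold, Tie1 1.51-fold). The camera adjusted p of the collagen, glycoprotein, protease, tendon, macrophage and endothelial lists was 2.4e-12, 7.0e-13, 2.0e-08, 4.4e-04, 2.1e-09 and 4.8e-04, and adjusted p = 0.12, 0.12, 0.12, 0.21, 0.16 and 0.21 with an estimated correlation. Counting calls adjusted over the list alone, their counts of higher genes were the same.

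Slow-fibre genes rose from a low level: 9 of 14 were higher under overload (Tnni1 5.90-fold, Tpm3 2.27-fold) and 2 were lower, among them Myh7b (1.18-fold). Among developmental contractile genes Myh3 rose 5.85-fold and the embryonic light chain Myl4 4.06-fold, 7 of 11 rising. In the satellite cell and myogenic list 11 of 17 rose, Mymk by 3.43-fold, and Myod1 and Cdh15 fell 1.44-fold and 1.33-fold. Igf1 rose 4.53-fold and Igf2 5.05-fold, though the growth signalling list was not called (camera adjusted p = 0.49, median -0.07 and mean 0.28 on the log2 scale). 12 of 19 atrophy and proteolysis genes fell, Fbxo32 and the transcription factor Klf15 (2.05-fold) with the smallest p. By camera, adjusted p of the slow-fibre, developmental, myogenic and atrophy lists was 5.2e-04, 6.2e-04, 0.0010 and 0.0078, and adjusted p = 0.16, 0.12, 0.15 and 0.19 with an estimated correlation. Adjusted over the list alone, 3 instead of 2 myogenic genes fell and the other counts of these 4 lists were the same. Only 10 of 26 oxidative phosphorylation and citric acid cycle genes and 9 of 18 fatty acid oxidation genes fell (Ndufa9 1.39-fold, Mlycd 1.45-fold), the uncoupling protein gene Ucp3 rose 1.37-fold (adjusted p = 0.032), and neither list was called (camera adjusted p = 0.084 and 0.094). Counts adjusted over the list alone were the same. 14 of 16 glycolysis and glycogen genes fell by a median of 1.21-fold (camera adjusted p = 0.021, adjusted p = 0.56 with an estimated correlation).

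Further large falls were those of Mettl21e (5.13-fold), a muscle methyltransferase, Inmt (5.73-fold), Ttll7 (3.52-fold), the core circadian activator Arntl (3.42-fold), the glycogen-targeting phosphatase subunit Ppp1r3c (3.32-fold), the amino acid transporter Slc43a1 (3.27-fold), Klhl38 (3.22-fold) and Mss51 (3.14-fold). The basement membrane, proteoglycan, collagen processing, progenitor, smooth muscle and pericyte, proliferation, complement and interferon, chemokine and cytokine, immediate early and heat shock, and denervation lists were called higher (camera adjusted p = 6.2e-06, 1.6e-04, 8.7e-07, 7.0e-04, 0.0089, 7.5e-06, 5.6e-06, 1.6e-04, 0.015 and 0.011, and adjusted p = 0.12, 0.19, 0.16, 0.21, 0.31, 0.16, 0.16, 0.16, 0.25 and 0.21 with an estimated correlation). Of the 35 lists 21 were called by camera, 0 of them with an estimated correlation (11 at an unadjusted p of 0.05), and 30 by fry. With the arrays shifted to the same median, 3195 genes were higher and 7058 lower, against 3932 and 4857 as deposited.

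The third comparison asks how lack of myostatin changes untreated muscle. The clearest difference was in slow-fibre genes, which were lower in Mstn-/- muscle. The ventricular and slow light chain genes Myl2 and Myl3 were 6.58-fold and 5.43-fold lower (log2 -2.72 ± 0.21 and -2.44 ± 0.21, SE, n = 6 per group), and slow myosin heavy chain (Myh7) was 3.80-fold lower. The methyltransferase gene Mettl21e was 7.22-fold higher (log2 2.85 ± 0.20) and Odf3l2 by 2.23 on the log2 scale. In all, 3091 of 14499 genes differed, 1616 higher and 1475 lower, but only 52 by at least 2-fold, 23 higher and 29 lower. Shifted to the same median, the arrays gave 1877 higher and 1300 lower.

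Of 14 slow-fibre genes 13 were lower, with a median difference of 2.51-fold, and 14 were lower adjusted over the list alone. The list was called both with the preset correlation (camera adjusted p = 1.9e-17) and with an estimated correlation (adjusted p = 0.0022), as the single list for which that held in the 5 comparisons. Troponin genes Tnni1 and Tnnc1 were 3.46-fold and 2.94-fold lower, and the slow-fibre calcium pump Atp2a2 2.78-fold lower. The secreted peptide gene Ostn was 4.94-fold lower, the nicotinamide riboside kinase Nmrk2 3.30-fold, Lgi1 2.93-fold and the nuclear receptor Nr4a2 2.81-fold. 12 of 18 fatty acid oxidation genes were lower (Ucp3 2.06-fold, Lpl 1.56-fold), as were 7 of 12 mitochondrial and PPAR regulators (Ppargc1b log2 -0.59, Vegfa 1.51-fold) while Ppard was 1.17-fold higher. 7 of 10 tendon markers were lower (Chad 2.09-fold, Fmod 1.55-fold). 8 of 26 oxidative phosphorylation and citric acid cycle genes were lower, with Idh2 at 1.95-fold. 6 of 15 fast-fibre genes were higher, with small differences (Myoz1 1.27-fold, Pvalb 1.20-fold), and 1 was lower. The camera adjusted p of the fatty acid oxidation, regulator, tendon, oxidative phosphorylation and fast-fibre lists was 5.2e-07, 5.0e-04, 4.9e-04, 0.0082 and 0.017, and adjusted p = 0.53, 0.30, 0.53, 0.87 and 0.87 with an estimated correlation. Counting calls adjusted over the list alone, 15, 8, 8 and 8 genes of the first 4 were lower and 7 fast-fibre genes higher.

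Among the largest increases in Mstn-/- muscle, the glucocorticoid-induced chaperone Fkbp5 was 3.03-fold higher, the phosphoinositide kinase subunit Pik3r1 2.45-fold, the transcription factor Cebpd 2.34-fold and Ppp1r3c 2.45-fold. Dpep1, Kcnf1 and Lcn2 were 2.43-fold, 2.24-fold and 2.23-fold higher. The ubiquitin ligases Trim63 and Fbxo32 were 1.74-fold and 1.71-fold higher, with 7 of 19 atrophy genes higher. Of other cell types, 7 of 18 macrophage markers were higher (Lyz1 2.00-fold, Lyz2 1.81-fold), as were all 3 of 3 mast cell markers (the protease Cpa3 2.19-fold), and 6 of 12 endothelial markers were lower (Kdr 1.57-fold), as were 3 of 10 adipocyte markers (Fabp4 1.48-fold). By camera, adjusted p of the atrophy, macrophage, mast cell, endothelial and adipocyte lists was 0.0032, 3.1e-04, 6.3e-04, 0.013 and 0.0092, and adjusted p = 0.35, 0.70, 0.19, 0.70 and 0.70 with an estimated correlation. Adjusted over the list alone, 7 endothelial and 6 adipocyte markers were lower and the other counts were the same. Interstitial collagens did not differ as a list (1 of 16 lower, camera adjusted p = 0.27), the lower gene being Col12a1 (1.58-fold). Of the 35 lists 11 were called by camera, 1 with an estimated correlation, and 10 by fry.

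The fourth comparison asks how the genotypes differ once overloaded. Overloaded Mstn-/- muscle had lower collagen and slow-fibre transcripts and higher fast-fibre, glycolytic and mitochondrial transcripts than overloaded wildtype muscle. Myh7 was 6.23-fold lower (log2 -2.64 ± 0.26, SE, n = 6 per group), Myl2 5.65-fold lower (log2 -2.50 ± 0.21) and Mettl21e 5.55-fold higher (log2 2.47 ± 0.20). In all, 5293 of 14499 genes differed, 2540 higher and 2753 lower, 78 of them by at least 2-fold, 54 higher and 24 lower. The balance of higher and lower genes depended on the scaling, with 2867 higher and 2316 lower when the arrays were shifted to the same median and 2715 and 2692 after another quantile normalization.

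All 16 of 16 interstitial collagens were lower in Mstn-/- muscle, with a median log2 difference of -0.59 (Col11a1 1.74-fold, Col6a2 1.49-fold). 14 of 18 collagen processing genes were lower, P4ha3 by 2.34-fold and the collagen chaperone Serpinh1 by 1.55-fold, and so were 13 of 19 glycoproteins (Thbs3 1.82-fold, Fbln2 1.69-fold) and 8 of 10 tendon markers (Comp 2.04-fold, the tendon transcription factor Scx 1.82-fold). Lysyl oxidase (Lox), which cross-links collagen, was 2.38-fold lower, the prolyl hydroxylase P3h2 2.45-fold and aggrecan (Acan) 3.01-fold. Timp4 was 2.97-fold higher. The camera adjusted p of the collagen, processing, glycoprotein and tendon lists was 5.8e-09, 5.4e-06, 5.9e-05 and 4.0e-04, and adjusted p = 0.26, 0.30, 0.30 and 0.30 with an estimated correlation. Counts adjusted over the list alone were the same except for glycoproteins, where 2 instead of 1 were higher.

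12 of 14 slow-fibre genes were lower, with the troponins Tnnc1, Tnni1 and Tnnt1 at 3.73-fold, 2.49-fold and 2.45-fold. Outside that list, the light chain gene Myl6b was 2.61-fold and Myh3 2.80-fold lower. 11 of 15 fast-fibre genes were higher (Pvalb 1.99-fold, the fast myosin-binding protein Mybpc2 1.77-fold), as were 12 of 16 glycolysis and glycogen genes (Phkg1 2.61-fold, Pgm1 2.27-fold), 18 of 26 oxidative phosphorylation and citric acid cycle genes (Cox4i1 1.71-fold) and 13 of 18 fatty acid oxidation genes (Decr1 1.53-fold). Ppargc1a was 2.23-fold higher, but its list of mitochondrial and PPAR regulators was not called (list mean 8.70 in Mstn-/- and 8.60 in wildtype muscle). By camera, adjusted p of the slow-fibre, fast-fibre, glycolysis, oxidative phosphorylation and fatty acid oxidation lists was 2.2e-07, 5.6e-09, 5.2e-08, 5.2e-08 and 1.9e-05, and adjusted p = 0.19, 0.26, 0.30, 0.35 and 0.36 with an estimated correlation. Counting calls adjusted over the list alone, 12 slow-fibre genes were lower and 12, 12, 20 and 13 genes of the other lists higher. Of the genes with the largest increases, Mylk4 was 3.89-fold higher, the alcohol dehydrogenase Adh1 2.94-fold, Mss51 2.89-fold, the carbonic anhydrase Car14 2.86-fold, Gpt2 2.86-fold, Plcd4 2.82-fold, the glucose-phosphate transporter Slc37a4 2.81-fold and Klhl33 2.68-fold. Macrophage markers were not called as a list (4 of 18 lower, camera adjusted p = 0.12). The proteoglycan, protease, TGF-beta, proliferation and progenitor lists were called lower and the atrophy list higher (camera adjusted p = 4.9e-04, 0.0018, 0.012, 0.027, 0.0013 and 0.013, and adjusted p = 0.30, 0.30, 0.26, 0.52, 0.30 and 0.30 with an estimated correlation). Of the 35 lists 15 were called by camera, 0 with an estimated correlation (4 at an unadjusted p of 0.05), and 20 by fry.

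**Figure D3:**
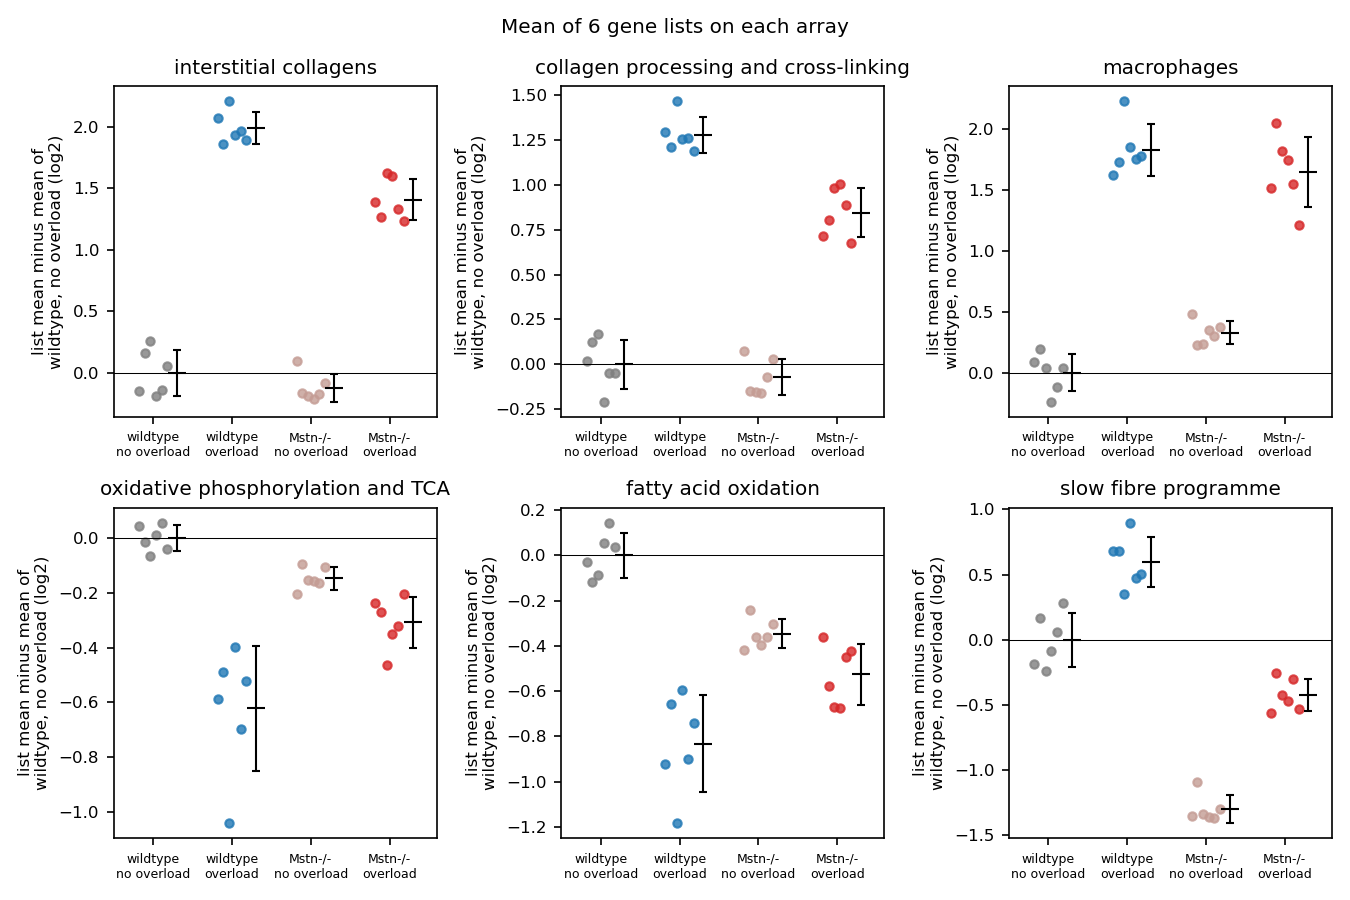
Mean log2 intensity of 6 gene lists on each array, minus the mean of the untreated wildtype group (vertical axis), by group (horizontal axis), 1 point per array with the group mean and SD in black. Interstitial collagens are lower on every overloaded Mstn-/- array than on every overloaded wildtype array, and replicate 3 of overloaded wildtype has the lowest mean of oxidative phosphorylation genes.

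The fifth comparison asks whether the response to overload depends on genotype. Many metabolic genes fell less, and some matrix, macrophage and progenitor genes rose less, in Mstn-/- muscle. Part of the metabolic difference lay in untreated muscle. The fatty acid oxidation list mean was 10.64 in untreated Mstn-/- against 10.99 in untreated wildtype muscle, and 10.46 against 10.16 under overload. For mitochondrial and PPAR regulators it was 8.89 against 9.21, and 8.70 against 8.60. For oxidative phosphorylation it was 11.79 against 11.93, and 11.63 against 11.31. The glycolysis list did not start lower (12.24 against 12.18). The overload response of all 18 of 18 fatty acid oxidation genes was higher in Mstn-/- than in wildtype muscle, by a median of 0.61 on the log2 scale. That of Ucp3 was 1.69 ± 0.25 higher (SE, n = 6 per group): the gene fell in wildtype, from 10.31 ± 0.22 to 9.06 ± 0.30, and rose in Mstn-/- muscle, from 9.26 ± 0.50 to 9.71 ± 0.29 (mean log2 intensity ± SD). The call of its rise in Mstn-/- muscle (limma adjusted p = 0.032) was lost in 2 of 8 settings and without any 1 of 5 arrays. In all, the response of 2516 of 14499 genes differed, 1293 higher and 1223 lower in Mstn-/- (1402 and 1219 with the arrays shifted to the same median), 90 of them by at least 2-fold. In 2035 of the 2516 (80.9%) the response was larger in wildtype, and 119 passed the test in both genotypes with opposite signs.

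21 of 26 oxidative phosphorylation and citric acid cycle genes (Ndufa4 0.68, Sdhd 0.57 on the log2 scale), 11 of 16 glycolysis and glycogen genes (Phkg1 1.17, Pgm1 1.12), 8 of 15 fast-fibre genes (Myh4 0.82, Pvalb 0.73) and 7 of 12 mitochondrial regulators (Ppargc1a 1.38, Ppara 1.08) had a higher response in Mstn-/-. 10 of 16 interstitial collagens (Col6a1 -0.62, Col5a3 -0.41), 10 of 18 collagen processing genes (P4ha3 -1.01, Bmp1 -0.59), 8 of 18 macrophage markers (Lyz2 -1.09, Csf1r -0.64) and 6 of 11 progenitor markers (Pdgfra -0.64, Pi16 -0.57) had a lower response. The camera adjusted p of these lists, beginning with fatty acid oxidation, was 3.3e-15, 3.3e-15, 6.3e-08, 1.2e-06, 2.0e-04, 1.9e-07, 4.6e-05, 5.1e-06 and 3.8e-05, and adjusted p = 0.22, 0.22, 0.23, 0.24, 0.22, 0.22, 0.30, 0.33 and 0.22 with an estimated correlation. Adjusted over the list alone, 18, 25, 12, 9 and 7 genes of the first 5 lists had a higher response, and 11, 12, 11 and 9 of the other 4 a lower one. Slow-fibre genes had a higher response in Mstn-/- in 5 of 14 (camera adjusted p = 0.022, adjusted p = 0.38 with an estimated correlation), Myl3 by 1.31 on the log2 scale, but the mean of the list did not pass an exact permutation test (difference 0.28, p = 0.60), whose spread includes the large genotype difference of this list. Endothelial markers had a higher response in 4 of 12 (camera adjusted p = 0.017, adjusted p = 0.46 with an estimated correlation). The basement membrane, glycoprotein, proteoglycan, protease, TGF-beta and mast cell lists had a lower and the adipocyte list a higher response (camera adjusted p = 0.0018, 0.017, 0.0079, 6.5e-05, 0.017, 0.0059 and 0.0049, and adjusted p = 0.25, 0.53, 0.38, 0.22, 0.22, 0.22 and 0.38 with an estimated correlation).

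The circadian clock gene Dbp had the smallest p of all responses. This output regulator of the clock fell 1.60-fold under overload in wildtype and rose 3.02-fold in Mstn-/- muscle, a difference of 2.27 ± 0.11 on the log2 scale (SE, n = 6 per group, adjusted p = 2.4e-13), and the response of the repressor Ciart differed by 2.31 ± 0.24. The response of Arntl was -1.80 ± 0.11, its level being 8.25 ± 0.14 and 8.28 ± 0.07 in wildtype and 9.14 ± 0.15 and 7.37 ± 0.19 in Mstn-/- muscle. Ostn and Mylk4 fell less in Mstn-/- (differences of 1.73 and 1.68). Meg3, Acan and the matricellular gene Ccn3 rose less (differences of -1.33, -1.45 and -1.64), and the B cell chemokine Cxcl13 had a difference in response of -1.99 ± 0.36. Of the 35 lists 18 were called by camera, 0 with an estimated correlation (8 at an unadjusted p of 0.05), and 17 by fry.

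**Figure D4:**
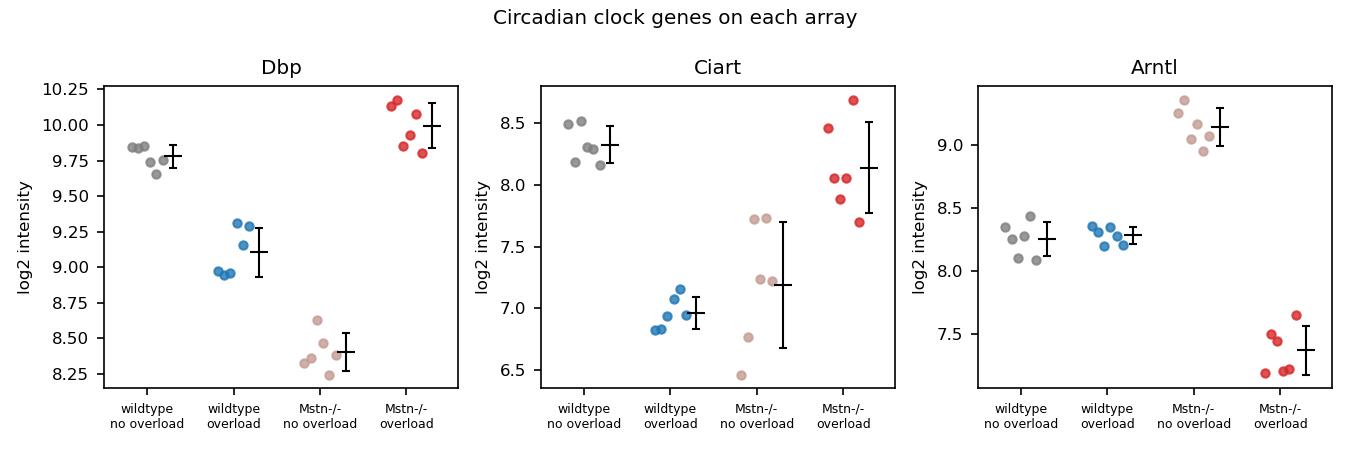
Log2 intensity (vertical axis) of the clock genes Dbp, Ciart and Arntl on each array by group (horizontal axis), 1 point per array with the group mean and SD in black. Dbp and Arntl move in opposite directions between the 2 Mstn-/- groups.

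Across genes, the overload responses of the 2 genotypes were closely related, with Pearson r = 0.908 and Spearman rho = 0.864 over 14499 genes, which are not independent replicates. The slope of the Mstn-/- on the wildtype response through the origin (total least squares) was 0.776, and 86.4% of genes had the same sign. Of the 7288 genes that passed in both genotypes, 3443 rose and 3726 fell in both, where independent lists would share 1192 and 1730. Myh3, Cthrc1 and Col3a1 lay below the line of equal responses and Mest on it. The genotype difference in untreated muscle was not related across genes to the wildtype overload response: Pearson r was 0.0024 with covariance 2.9e-04. Unchanged groups sharing the same controls gave a covariance of 0.0035 in 100 simulations. Their r of 0.5004 is not the value to expect here, since the simulated groups held no real differences. With the untreated wildtype arrays split into 2 separate sets the mean r was -0.028, between -0.173 and 0.123 over 20 splits. The genotype differences without and under overload, which share no arrays, had r = 0.417 across genes, a comparison added after seeing the data, and Myl2, Myh7 and Mettl21e differed in both.

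**Figure D5:**
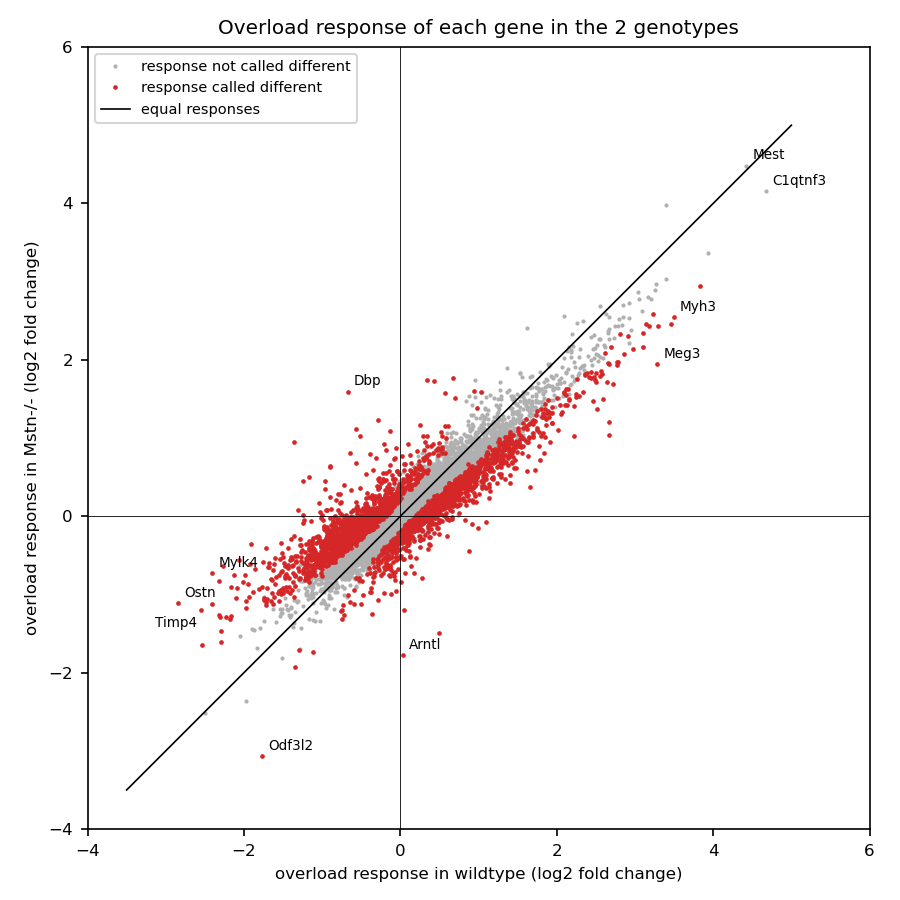
Log2 fold change under overload in Mstn-/- (vertical axis) against wildtype (horizontal axis) muscle for each of 14499 genes, with the 2516 genes whose response differed in red and the line of equal responses in black. Falling genes in red lie mostly above the line and rising ones mostly below it, which is a smaller response in Mstn-/-.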

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

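The tests of explanations and the splits of the arrays in this part were chosen after the results were seen. The test of single arrays and the test of the difference between the 2 genotypes' responses were set before the data were examined.

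Clock genes differed between the groups. The mean of 10 clock genes of the day arm minus that of 4 of the night arm (log2) was 0.85 ± 0.09 (SD, n = 6) in untreated wildtype, 0.37 ± 0.14 in overloaded wildtype, -0.23 ± 0.13 in untreated and 1.14 ± 0.12 in overloaded Mstn-/- muscle. These genes were chosen after their values had been seen, so no p is given for the arms. The response of 11 of the 14 differed between the genotypes by the interaction test (adjusted over all 14499 genes). For those genes 1 by 1, an equal effect of overload in both genotypes is argued against. The day arm minus the night arm responded with opposite signs (-0.47 in wildtype and 1.36 in Mstn-/-). The count of 11 is no evidence about clock genes in general, since the genes were chosen after their values were seen. Without overload 11 of the 14 already differed between the genotypes, again a count over chosen genes (day arm minus night arm -1.07). For those genes 1 by 1, overload in Mstn-/- muscle as the single source of the differences between groups is argued against. A response to overload in Mstn-/- muscle alone, beside the difference without overload, is not. Arntl responded by 0.03 in wildtype (limma adjusted p = 0.75) and by -1.77 in Mstn-/- muscle (adjusted p = 6.5e-15). In wildtype 9 of the 10 day arm genes and 2 of the 4 night arm genes did respond. Sampling at different times of day stays open as an explanation, since the arms went opposite ways in 3 of the 4 comparisons of 2 groups. In 1 of these, genotype under overload, the night arm moved little (-0.17), with 1 of its 4 genes higher and 2 lower, and under overload in wildtype both arms fell (-0.61 and -0.13). A lasting change of the clock by genotype and load together stays open too, and the sampling times that would part them are not given in the sources used here. Different sampling times could also contribute to the other differences between groups in this report, those in metabolic genes included, which was not tested.

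Slow-fibre genes were lower in Mstn-/- muscle. Soleus tissue left on the wildtype control muscles could add slow-fibre transcripts, but the list was lower also where the soleus had been removed (difference under overload -1.02, exact permutation p = 0.0022, the smallest that 924 arrangements can give; without overload -1.30). Fewer slow fibres, or fewer slow-fibre transcripts per fibre, in Mstn-/- muscle stay open as hypotheses and were not tested here.

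The overload response was smaller in Mstn-/- muscle in 2035 of the 2516 genes whose response differed. Compressed signal on the Mstn-/- arrays as the single cause is argued against by the 481 of these genes that responded more in Mstn-/- muscle. The 5% of false calls that the threshold allows would be 125.8. Compression beside larger responses of some genes would also give such a number, so a part of it in the smaller responses stays open. With a smaller shift from fibres to other cells the markers of all other cells would rise less in Mstn-/- muscle. Of 11 lists of cell type markers, the response of 3 was lower in Mstn-/- by an exact permutation test (macrophages, mast cells and fibro-adipogenic progenitors). That of endothelium was higher (0.24 in wildtype and 0.41 in Mstn-/-, exact permutation p = 0.049, camera adjusted p = 0.46 with an estimated correlation). The other 7 did not pass. Of these, cartilage and bone (0.44 and 0.21), neutrophils (0.63 and 0.53) and tendon (0.92 and 0.84) rose less in Mstn-/- muscle. Smooth muscle and pericytes (0.40 and 0.44) and lymphocytes (0.24 and 0.24) did not. Adipocyte (-0.43 and -0.01) and Schwann cell and nerve markers (-0.14 and -0.10) fell less. The spread of this test includes the genotype difference of a list, which can hide a difference in response. The endothelial difference lies in untreated muscle (-0.16, exact permutation p = 0.017; under overload 0.01, p = 0.91) and is narrow, so a smaller shift stays open, though these lists did not move alike. Macrophage markers rose by 1.83 and 1.32 but started 0.33 higher in untreated Mstn-/- muscle (exact permutation p = 0.0022, under overload -0.18, p = 0.25), so a different starting level stays open for them. The 3 mast cell markers tested started 0.70 higher in untreated Mstn-/- muscle (exact permutation p = 0.0022, under overload 0.03, p = 0.79). A different starting level stays open for mast cells too. Progenitor markers rose by 1.15 and 0.68 from 9.31 and 9.36 (difference 0.05, exact permutation p = 0.55) and were lower under overload (-0.42, p = 0.0022), which goes against a different starting level for these cells. A lower load relative to the size of the muscle was not tested.

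Of 100 splits of the 12 arrays of each comparison of 2 groups, the real split among them, only the real split gave as many genes. A share of 1 in 100 is the smallest that this number of splits can give. Such splits cannot part the groups from dates of surgery, sampling or scanning that might coincide with them. The real split gave 9000 genes for overload in wildtype (highest other 4054), 9277 for overload in Mstn-/- (4148), 3395 for genotype without overload (84) and 4698 for genotype under overload (29), in fits of the 2 groups alone. For the difference between responses, the genotype and overload effects were first removed and genotype labels were then permuted within each condition. The real value was 2516 and the highest of the permuted ones 160. Of the other splits for overload, 3 gave any genes in wildtype and 1 in Mstn-/- muscle.

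Single arrays lay apart from the other 5 of their group in 50 of 776 groups tested (6.44%), over 159 named genes and 35 lists, where chance gives about 5%. The values are log2 differences from the mean of the other 5. Overloaded wildtype replicate 3: the matrix proteoglycans list 0.21, the matrix proteases and inhibitors list 0.26, the fast fibre programme list -0.33, the glycolysis and glycogen list -0.52, the neutrophils list 1.54, the fibro-adipogenic progenitors list 0.24, the tendon list 0.34, Sfrp2 0.74, Tgfbr2 0.26, Tpm3 0.31, Cdh15 -0.24, Klf15 -0.30, Igf1 0.53, Mlycd -0.37, Trim63 -0.61, Fmod 0.39, Ndufa4 -0.38, Col6a2 0.29 and Zbtb16 -0.74. Untreated Mstn-/- replicate 1: the basement membrane list 0.18, the glycolysis and glycogen list -0.039, Mmp14 0.23, Col6a3 0.45, Tgfbr2 0.24, Ndufa9 -0.48 and Bmp1 0.33. Untreated wildtype replicate 4: the tendon list -0.65, Thbs4 -0.67, Chad -0.997, Fmod -0.80, Comp -0.88 and P3h2 -0.60. Untreated wildtype replicate 2: the smooth muscle and pericytes list 0.67, Cthrc1 0.57, Cox4i1 0.24 and Ccn3 1.38. Untreated Mstn-/- replicate 2: the slow fibre programme list 0.25 and Klhl33 0.42. Overloaded Mstn-/- replicate 5: Cd163 0.39 and Myl2 1.28. Untreated wildtype replicate 5: Lpl 0.26 and Odf3l2 -0.39. Overloaded wildtype replicate 2: Mymk -0.40 and Mettl21e 0.43. Overloaded Mstn-/- replicate 1: Cox4i1 0.44. Overloaded Mstn-/- replicate 3: Car14 -0.47. Overloaded Mstn-/- replicate 4: the ribosome biogenesis list -0.078. Overloaded Mstn-/- replicate 6: Adhfe1 0.55. Untreated wildtype replicate 3: Myl2 -0.20. Overloaded wildtype replicate 5: Mss51 -0.36. Replicate 3 of overloaded wildtype had the most, with matrix lists higher and glycolytic and fast-fibre lists lower than on its group's other arrays. Without it 9135 genes changed by overload in wildtype. The count for genotype without overload, which this array enters only through the pooled spread, was 3296. For 2 other comparisons that it enters, leaving out any single array gave 4668 to 5739 genes (genotype under overload) and 2094 to 2755 (difference in response).

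The response to overload differed between the genotypes by the interaction test for 2516 genes, among them 103 of the named ones. The values below are log2 responses of Mstn-/- minus wildtype muscle. The lists are those called by camera at the preset correlation, and 0 of them were called with an estimated correlation. Lists with a higher median response were slow fibre programme 0.20, fast fibre programme 0.21, glycolysis and glycogen 0.39, oxidative phosphorylation and TCA 0.43, fatty acid oxidation 0.61, mitochondrial and PPAR regulators 0.40, endothelium 0.19 and adipocytes 0.37. Lists with a lower one were interstitial collagens -0.47, basement membrane -0.21, matrix glycoproteins -0.28, matrix proteoglycans -0.23, collagen processing and cross-linking -0.32, matrix proteases and inhibitors -0.41, TGF-beta and activin signalling -0.14, macrophages -0.57, mast cells -0.45 and fibro-adipogenic progenitors -0.45.

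Among named genes, some responses were higher in Mstn-/- muscle. They were Ciart 2.31, Dbp 2.27, Ostn 1.73, Ucp3 1.69, Mylk4 1.68, Per3 1.55, Nmrk2 1.52, Plcd4 1.498, Ppargc1a 1.38, Klhl33 1.38 and Timp4 1.35. Further higher ones were Myl3 1.31, Adhfe1 1.29, Slc37a4 1.19, Mstn 1.18, Phkg1 1.17, Pgm1 1.12, Nr4a2 1.09, Ppara 1.08, Gpt2 1.05, Per2 1.03 and Gdap1 1.02. Further higher ones were Lgi1 1.003, Mss51 0.89, Irs2 0.84, Pfkfb3 0.83, Myh4 0.82, Lpl 0.82, Idh2 0.77, Fabp4 0.74, Idh3a 0.74, Pvalb 0.73 and Decr1 0.68. Further higher ones were Ndufa4 0.68, Atp2a2 0.67, Phka1 0.66, Tsc22d3 0.64, Eci1 0.63, Mybpc2 0.61, Sdhd 0.57, Adh1 0.55, Myoz1 0.54, Cox4i1 0.52 and Cox5a 0.51. Further higher ones were Ndufa9 0.47, Vegfa 0.46, Actn3 0.46, Vtn 0.45, Pln 0.42, Ppargc1b 0.41, Kdr 0.40, Mlycd 0.39, Esam 0.31, Flt1 0.30 and Tie1 0.24. Without replicate 5 of untreated wildtype Tie1 lost its call (adjusted p = 0.051). Others were lower. Those lower were Cxcl13 -1.99, Arntl -1.80, Ccn3 -1.64, Acan -1.45, Meg3 -1.33, Lcn2 -1.33, Odf3l2 -1.30, Pik3r1 -1.24, Cpa3 -1.14, Lox -1.14, Lyz2 -1.09, Myl6b -1.06 and P4ha3 -1.01. Further lower ones were Mmp2 -0.99, Myh3 -0.95, Mmp14 -0.94, Cthrc1 -0.89, Kcnf1 -0.87, Fbln2 -0.86, Thbs3 -0.81, Aspn -0.76, Mfap5 -0.74, Tgfbr2 -0.66, Myod1 -0.65, Csf1r -0.64 and Pdgfra -0.64. Further lower ones were Vcan -0.64, Col6a1 -0.62, Ppp1r3c -0.61, Col3a1 -0.59, Bmp1 -0.59, Dpep1 -0.58, Fbxo32 -0.58, Fkbp5 -0.57, Pi16 -0.57, Tnnt2 -0.57, Col11a1 -0.56, Lamb1 -0.54 and Cebpd -0.53. Further lower ones were Col6a3 -0.53, Loxl1 -0.52, Col6a2 -0.48, Igf2 -0.48, Scx -0.45, Slc43a1 -0.42, Col5a3 -0.41, Cdh15 -0.25 and Ppard -0.23.

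Outside the comparisons, 3378 of 11799 probe sets without a gene symbol changed under overload in wildtype.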

How the results depend on the processing

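Removal of the 3 arrays with the lowest array weight and the correlation of the 2 genotype effects were chosen after seeing the data; the other alternatives were set before the data were examined.

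The number of genes moved by more than 1.5 times with 2 choices. With every probe set tested, 15278 of 34760 changed under overload in wildtype (9560 of 14499 genes as reported) and 13997 in Mstn-/- (8789 as reported), and the correlation between the overload responses was 0.858 (0.908). With a minimum fold of 1.5 there were 3125 and 2042 genes for overload in wildtype and in Mstn-/-, 247 and 528 for genotype without and under overload, and 509 for the difference in response (9560, 8789, 3091, 5293 and 2516 without it).

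Shifted to the same median, 3633 genes were higher and 7004 lower under overload in wildtype (34.2% higher against 46.0%), and 3195 and 7058 in Mstn-/- (31.2% against 44.7%); the median log2 change moved by -0.0868 and -0.0814. For genotype under overload the balance turned, from 48.0% higher to 55.3%. No named gene or list changed direction while called.

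Leaving out single arrays gave 9135 to 9711 and 8122 to 8984 genes for overload in wildtype and Mstn-/-, 4668 to 5739 and 2597 to 3296 for genotype under and without overload, and 2094 to 2755 for the difference in response. The correlations were 0.901 to 0.912 between overload responses, -0.041 to 0.051 between genotype and wildtype overload effects and 0.384 to 0.448 between genotype effects. Without replicates 3 and 4 of overloaded wildtype and 1 of untreated wildtype (array weights 0.391, 0.387 and 0.438) there were 8744, 9343, 3831, 5510 and 2156 genes in the order of the 5 comparisons.

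With the replicate block the counts were 9512, 8688, 3004, 5219 and 2440. Arrays of the same number were not alike (correlations of deviations -0.412 to 0.363, mean 0.0157, 9 of 36 pairs over 0.1, 4 of 24 arrays closest to their own number), so the numbers do not pair the arrays.

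With an estimated correlation 89 of 175 list results lost their call and the other 86 were the same. Only 1 of these 86 was a call, that of the slow-fibre list for genotype without overload. The rest had not been called at the preset correlation either. With fry 25 gained a call and 4 lost one. Under the other 9 settings, the slow-fibre list under overload in wildtype (camera adjusted p = 0.057) passed in 5 (0.015 to 0.10), the oxidative phosphorylation list under overload in Mstn-/- in 2 (0.032 to 0.37), and the glycolysis list there failed in 1 (0.0038 to 0.10). Under overload in wildtype the integrin and sarcolemmal linkage list lost its call in 3 (camera adjusted p up to 0.080). The smooth muscle and pericyte list there lost it in 4 (up to 0.083). Other lists near the threshold changed call in up to 5. Single genes were rerun only in the comparisons for which the naming rule picked them. Not every difference in response listed above was therefore checked. Of the rerun calls given in the report, that of Ucp3 under overload in Mstn-/- was lost in 2 of 8 settings. It was also lost without any 1 of 5 arrays (replicates 1 and 2 of untreated and 1, 5 and 6 of overloaded Mstn-/-). Its limma adjusted p lay between 0.0077 and 0.12, and was 0.12 without replicate 1 of untreated Mstn-/-. The difference in response of Tie1 (adjusted p = 0.025) lost its call with another quantile normalization (0.069) and without replicate 5 of untreated wildtype (0.051).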

Other observations

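The 4 gene lists of this part were written after the values had been seen, and their genes were chosen then too. They include genes already seen to differ, so no p is given for a list, and the counts describe the chosen genes only.

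Of 12 glucocorticoid-responsive genes 10 were higher in Mstn-/- than in wildtype muscle without overload (median log2 difference 0.66) and 11 under overload (median 0.75). Without and under overload Fkbp5 was 3.03-fold and 2.04-fold higher, the glutamine synthetase gene Glul 2.03-fold and 1.87-fold, Cebpd 2.34-fold and 1.63-fold, and the leucine zipper gene Tsc22d3 1.28-fold and 1.99-fold. Under overload 7 of the 12 fell in wildtype and 7 in Mstn-/- muscle, the transcription factor Zbtb16 by 2.75-fold and 2.20-fold. The mean difference between the genotypes kept its direction under overload (log2 0.69 without and 0.66 under overload). That of the day arm minus the night arm of the clock genes changed sign (-1.07 and 0.76). Single glucocorticoid-responsive genes did not all hold. The difference for Pik3r1 went from 1.29 to 0.05 and for Sgk1 from -0.16 to 0.80. By the interaction test the overload response was higher in Mstn-/- for 2 of the 12, lower for 3 and not called different for 7.

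Of 15 imprinted growth genes 13 rose under overload in wildtype and 14 in Mstn-/- muscle. Mest rose 21.4-fold and 22.4-fold, the zinc finger gene Plagl1 7.56-fold and 6.63-fold, Igf2 7.02-fold and 5.05-fold and the Notch ligand relative Dlk1 4.36-fold and 4.32-fold. Meg3 rose 9.72-fold in wildtype and 3.86-fold in Mstn-/- muscle, and was 2.05-fold higher in untreated Mstn-/- than in untreated wildtype muscle.

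Of the clock genes, 9 of 10 of the day arm fell under overload in wildtype, while in Mstn-/- muscle 6 rose and 1 fell. Per2 fell 1.13-fold in wildtype and rose 1.80-fold in Mstn-/-, and Per3 fell 1.43-fold and rose 2.04-fold. The nuclear receptor Nr1d1 fell in both, 1.67-fold and 1.46-fold. The night arm (4 genes) fell in all 4 in Mstn-/- muscle and in 2 in wildtype.

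Among the 11799 probe sets without a gene symbol 28.6% changed under overload in wildtype, 1351 higher and 2027 lower, against 52.6% of those with a symbol. Their median log2 intensity was 6.45 against 7.52, and no gene name was assigned to them here.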
